A study of Mus musculus with 15 samples.

How the data were processed

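The 15 libraries were made from mouse bone marrow derived macrophages with a stranded TruSeq RNA kit, per the labels' protocols. Marrow cells were grown for 7 days in M-CSF at 10 ng/ml and then left untreated, given heme-albumin at 200 or 400 µM, or polarized with IL-4 or IFN-γ at 10 ng/ml. Heme-albumin was hemin bound to human serum albumin. The treatment tag of the higher dose reads 400, 401 and 402 µM in replicates 1, 2 and 3, while the titles and the protocol give 400 µM, which was used for all 3. The time under treatment was not given in the sources used here.

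The values are raw counts per gene as deposited, in 1 table of 15 columns. STAR 2.7.0e, SAMtools 1.9 and featureCounts (version not given in the sources used here) and the build GRCm38.p5 are named in the submitters' processing notes. The annotation and the strand setting of the counting were not given in the sources used here, so a gene and its antisense partner, or a gene and an overlapping one, cannot be told apart with certainty. Reads shared by near-identical copies are likewise uncertain. Of 25700 gene identifiers, 25587 were matched to a symbol and position in GENCODE M21 (GRCm38), and 113 were not.

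Totals ran from 8427352 to 28587416 counts, so a gene at 1 CPM rests on few counts in the smallest library. The 10 most abundant genes took 10.8 to 11.7% of the counts in controls and 16.0 to 20.5% with heme-albumin. Hemoglobin genes took at most 1.43e-04% of a library. Replicates of a group differed by a chi-square per degree of freedom of 7.12 to 135, so none was a copy of another in its group.

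Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 11883, libraries were scaled by TMM (factors 0.886 to 1.12), and 1 quasi-likelihood model with a mean per group was fitted to all 15 libraries. The 7 comparisons were each treatment against control, the doses against each other, and heme-albumin 400 against IL-4 and against IFN-γ. Adjusted p-values are Benjamini-Hochberg within a comparison, with a threshold of 0.05. Of 34 fixed gene lists, the 31 with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move on balance 1 way and compares it with no other genes. Adjusted p-values in the text are edgeR's for genes and camera's for lists unless another tool is named. The list genes Ifi30, Ear11, Aldoa and Ahsp were not used here.

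Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls by fitted fold change (5 each in the 2 direct comparisons) among genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between replicates, passing over predicted genes. It added up to 4 members of smallest p from each list called or described, and 26 marker genes where they bore on the text. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

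The columns carry 3 dates, 1 per replicate number in every group, so the numbers pair the samples, although what a date marks was not given in the sources used here. In a check, 30 pairs of libraries with the same number in different groups had a median correlation of their deviations from the group means of 0.130 (range -0.154 to 0.454), against -0.0614 for 60 other pairs. The correlation was over 0.1 in 18 of the 30, and 14 of 15 libraries correlated best with their own number. The fit with the number as a block was an alternative.

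Alternatives were DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors in edgeR, no filter, a filter of 5 CPM in 3 libraries, only the 6 libraries compared, the replicate block, and leaving out each library. Added later were leaving out both libraries that stood apart from their groups (heme-albumin 400 replicate 2 and IFN-γ replicate 3) and the block with only the 6 libraries compared. On simulated counts for heme-albumin 400 against control over 11883 genes, the test recovered 12 of 50 genes changed 1.5-fold, 37 of 50 changed 2-fold, 48 of 50 changed 4-fold and 47 of 50 changed 8-fold, and 11 of 155 calls were unchanged genes (7.10%). A list raised 1.5-fold was called by camera, and 0 of 28 other lists were. Genes were simulated independently of each other, so this could not show how camera behaves for lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.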

Results

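RNA of 15 macrophage cultures was sequenced from stranded TruSeq libraries and counted per gene. They came from mouse bone marrow cells grown into macrophages for 7 days in M-CSF at 10 ng/ml. The 5 groups of 3 libraries were untreated controls, heme-albumin at 200 µM, heme-albumin at 400 µM, IL-4 at 10 ng/ml (termed M2) and IFN-γ at 10 ng/ml (termed M1). Heme-albumin, heme carried on albumin, stands in the labels for macrophages that have taken up red blood cells. Total counts were 13937722, 15252357 and 8427352 in controls 1 to 3, 14329361, 12705027 and 9819362 at 200 µM, 9109301, 9069999 and 13182889 at 400 µM, 15945686, 18384506 and 28587416 with IL-4, and 16706436, 22494832 and 16398891 with IFN-γ. Of 25700 genes, 11883 carried enough counts to be tested.

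Changes are log2 fold changes ± SE, and levels are CPM (counts scaled to the library total) ± SD, with n = 3 libraries per group. A gene rose or fell when edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. A gene with no counts in 1 group has a lower bound in place of a fold change, set at 3 counts over that group. A gene with 1 to 3 counts in a group has a ratio with a 95% counting interval. Such intervals and floors cover counting error only. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. Coordinates are those of GRCm38, where Bag3, Ciita, Clec9a, Cp, Cx3cr1, Cxcl10, Dusp1, Fpr2, Ftl1, Gas6, Gbp10, Gbp4, Gbp8, Gp1bb, H2-DMa, Hpgd, Hsd11b1, Il18bp, Irf1, Lpcat3, Me1, Mmp12, Mmp19, Mvd, Oas2, Pfkfb3, Pkm, Pltp, Psmb9, Rtp4, Sesn1, Slc7a11, Smpd3, Srebf1, Stab1, Tap1, Tgtp1, Tk1, Tmem176a and Tmem176b overlap another gene, so that their counts are uncertain. A list is given with the numbers of tested members that rose and fell, its median log2 fold change (also with members near 0 counts at their bounds where that differs) and the test by camera. Where an alternative ended a call, or leaving out 1 library or the replicate block added one, its adjusted p stands in parentheses after the library left out, followed by the range over the alternatives.

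Heme-albumin at 400 µM was compared with no treatment to see what heme loading does to these macrophages. Hmox1, the enzyme that breaks heme down (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), rose by 4.76 ± 0.29 (adjusted p = 2.76e-07), from 867 ± 219 to 23500 ± 1791 CPM. The iron exporter Slc40a1 (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523) rose (3.75 ± 0.43) and the transferrin receptor Tfrc fell (-3.34 ± 0.27). The cystine transporter Slc7a11 rose by 5.89 ± 1.09, while the fatty acid desaturase Scd1 fell (-6.84 ± 0.77), from 202 ± 55.0 to 1.81 ± 0.822 CPM. In all, 1740 genes rose and 1277 fell, 807 and 389 of them by at least 2-fold.

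Antioxidant genes rose together. Of the NRF2 targets, 24 of 24 rose and 0 fell (24 and 0 adjusted over the list alone, median 2.18, adjusted p = 8.30e-35, or adjusted p = 0.0248 with an estimated correlation). Examples were Nqo1 (5.02 ± 0.41), Aox1 (4.82 ± 0.35), Me1 (2.30 ± 0.18) and Gclm (3.58 ± 0.40). Of the heme and iron handling genes, 12 of 26 rose and 4 fell (13 and 5 adjusted over the list alone, median 0.35, adjusted p = 6.38e-04, or adjusted p = 0.2998 with an estimated correlation). Beside Hmox1, Slc40a1 and Tfrc, the porphyrin transporter Abcb6 rose (2.01 ± 0.11), as did the ferritin chains Fth1 (1.64 ± 0.28) and Ftl1 (1.26 ± 0.22), which have near-identical copies in the genome and are uncertain. Spic, a transcription factor of red pulp macrophages (ENSMUSG00000004359, chromosome 10, 88674772 to 88685015), rose as well (4.92 ± 1.02). Of the proteasome subunits, 21 of 31 rose and 0 fell (23 and 1 adjusted over the list alone, median 0.39, adjusted p = 1.00e-07, or adjusted p = 0.238 with an estimated correlation). Psma5 (1.11 ± 0.10), Psmd11 (1.11 ± 0.11) and Psma7 (0.65 ± 0.08) were examples. Of the matrix remodelling genes, 8 of 16 rose and 2 fell (9 and 2 adjusted over the list alone, median 1.18, adjusted p = 3.38e-04, or adjusted p = 0.0554 with an estimated correlation). Mmp8 (3.38 ± 0.33), Mmp19 (1.97 ± 0.13) and Plaur (1.29 ± 0.14) were higher.

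Of the type I interferon response genes, 0 of 20 rose and 18 fell (0 and 19 adjusted over the list alone, median -2.17, adjusted p = 2.12e-23, or adjusted p = 0.0554 with an estimated correlation). Ifit3 (-3.72 ± 0.39), Cmpk2 (-3.08 ± 0.28) and Stat2 (-1.51 ± 0.13) were examples. Of the interferon-gamma response genes, 1 of 26 rose and 13 fell (1 and 13 adjusted over the list alone, median -1.17 or -1.01 at the bounds, adjusted p = 6.53e-07, or adjusted p = 0.238 with an estimated correlation). Irf1 (-0.97 ± 0.13) and Iigp1 (76.4-fold lower, counting interval 13.4 to 3048) were examples. Of the MHC class I presentation genes, 0 of 16 rose and 9 fell (0 and 11 adjusted over the list alone, median -0.52, adjusted p = 3.01e-04, or adjusted p = 0.483 with an estimated correlation). H2-Q4 (-1.30 ± 0.23), Psmb9 (-0.99 ± 0.17) and Tap1 (-0.91 ± 0.17) were examples. H2-Q4 and Iigp1 have close relatives and are uncertain. Of the cholesterol synthesis genes, 0 of 22 rose and 17 fell (0 and 20 adjusted over the list alone, median -1.43, adjusted p = 8.25e-13, or adjusted p = 0.340 with an estimated correlation). Nsdhl (-1.52 ± 0.17), Sc5d (-1.45 ± 0.19) and Mvd (-1.84 ± 0.26) were lower. Of the LXR targets, which serve lipid efflux and desaturation, 0 of 13 rose and 8 fell (1 and 9 adjusted over the list alone, median -0.90, adjusted p = 1.75e-04, or adjusted p = 0.0248 with an estimated correlation). Abca1 (-1.91 ± 0.29), Scd2 (-3.71 ± 0.65) and Lpcat3 (-0.54 ± 0.11) were lower. Of the cell cycle genes, 0 of 24 rose and 1 fell (0 and 0 adjusted over the list alone, median -0.83, adjusted p = 0.00684, or adjusted p = 0.802 with an estimated correlation). E2f1 fell (-0.57 ± 0.17), and Mcm4 (-0.88 ± 0.34), Tk1 (-1.42 ± 0.62) and Mcm3 (-0.86 ± 0.38) did not pass. E2f1 lost its call without control 2 (0.0692), control 3 (0.0733) and 400 µM 2 (0.108), range 0.0192 to 0.108. Mcm4 gained a call with the replicate block (0.0324), range 0.0143 to 0.250. The cell cycle list lost its call without 400 µM 2 (0.0923), range 8.82e-04 to 0.0923. Phagocytic and scavenger receptors gained a camera call without 400 µM 3 (0.0472), range 0.0472 to 0.240.

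Esam was among the large rises. This gene of an endothelial adhesion molecule (ENSMUSG00000001946, chromosome 9, 37528078 to 37538319) rose from 0.195 ± 0.0596 to 225 ± 16.6 CPM (10.13 ± 0.21). Others were Six4 (at least 112-fold higher), Ptpn14 (at least 77.8-fold higher), Adh7 (at least 70.0-fold higher), Il1f9 (8.79 ± 1.57), Mt3 (466-fold higher, counting interval 83.0 to 18444) and Arnt2 (7.29 ± 0.60). Large falls, beside Scd1 and Iigp1, were Cbr2 (-5.54 ± 0.71), Arg1 (40.8-fold lower, counting interval 7.02 to 1639), Ifi208 (31.1-fold lower, counting interval 10.4 to 153), Cp (24.8-fold lower, counting interval 8.24 to 122), Tmem176a (-4.03 ± 0.66) and Smpd3 (-3.99 ± 0.52). Among markers of polarised macrophages, the mannose receptor Mrc1 fell (-3.22 ± 0.64), as did H2-Aa (-1.75 ± 0.38) and Cd40 (-1.36 ± 0.36), while Cd86 (0.36 ± 0.21), H2-Ab1 (-0.70 ± 0.42), Cd74 (-0.09 ± 0.29), Ciita (-1.53 ± 0.64), Chil3 (-0.32 ± 1.11), Tnf (-0.08 ± 0.12), Il1b (-2.16 ± 1.13) and Il10 (0.50 ± 0.51) did not pass. Retnla had at most 3 counts in either group. The scavenger receptor Marco stood at 1230.3 ± 943 against 195 ± 133 CPM and did not pass (2.65 ± 1.24, adjusted p = 0.137). Nos2 and Cxcl9 had no counts at 400 µM (at least 2.91-fold lower and at least 4.85-fold lower) and did not pass. Ptpn14 lost its call without control 1 (0.0897), control 2 (0.0932), control 3 (0.0769) and 400 µM 2 (0.126), without both libraries that stood apart (0.0987) and with no filter, range 0.0180 to 0.126. Adh7 lost its call without both libraries that stood apart (0.0522), range 5.62e-04 to 0.0522. Arg1 lost its call without control 1 (0.0648) and 400 µM 2 (0.0703), 400 µM 3 (0.0697), range 0.00258 to 0.0703. Il1b gained a call with the replicate block (0.0308), range 0.0308 to 0.373. Cd74 changed sign without control 1 (0.04) and 400 µM 2 (0.07). Chil3 changed sign without control 1 (0.84) and 400 µM 2 (0.03).

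The other 21 lists tested were not called at 400 µM. Among macrophage functions, the IL-4 response genes gave 9 of 27 rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 0.347). Cdh1 (4.34 ± 0.35) and Ear2 (2.78 ± 0.72) were higher. MHC class II presentation gave 2 of 11 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.640), with H2-DMb1 (0.52 ± 0.12) and H2-DMa (0.75 ± 0.20) higher and H2-Eb1 (-2.05 ± 0.40) lower. Costimulatory and checkpoint ligands gave 5 of 14 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.06, mean 0.24, test toward lower, adjusted p = 0.983), with Tnfsf4 (3.65 ± 0.65) and Cd80 (0.64 ± 0.09) higher and Lgals9 (-1.29 ± 0.11) lower. Inflammatory cytokines gave 3 of 19 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.873), with the prostaglandin synthase Ptgs2 (5.75 ± 0.63) and Cxcl3 (5.33 ± 1.44) higher and Ccl12 (-3.86 ± 0.94) lower. Anti-inflammatory mediators gave 1 of 16 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.21, mean 0.10, test toward lower, adjusted p = 0.775), with Dusp1 (1.72 ± 0.41) higher and Tsc22d3 (-1.39 ± 0.18) lower. Tissue macrophage identity genes gave 6 of 15 rose and 4 fell (6 and 7 adjusted over the list alone, median -0.23, mean 0.64, test toward higher, adjusted p = 0.766). Treml4 (6.45 ± 0.70) and Cd5l (2.32 ± 0.45) were higher. Core macrophage genes gave 2 of 14 rose and 1 fell (3 and 3 adjusted over the list alone, adjusted p = 0.733), and phagocytic and scavenger receptors 3 of 22 rose and 9 fell (4 and 10 adjusted over the list alone, adjusted p = 0.147), with the fatty acid receptor Cd36 (2.27 ± 0.28) higher and Fcgr2b (-2.10 ± 0.25) and Gas6 (-2.16 ± 0.42) lower. Metal-responsive genes gave 3 of 6 rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.147), lysosome genes 6 of 25 rose and 5 fell (6 and 6 adjusted over the list alone, adjusted p = 0.983), with Ctsl (1.15 ± 0.14) and Plin2 (1.59 ± 0.20) higher. The integrated stress response gave 3 of 22 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.10, mean 0.03, test toward lower, adjusted p = 0.775), the unfolded protein response 1 of 17 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.243), heat shock genes 4 of 14 rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.156), with Hsph1 (1.31 ± 0.17) and Bag3 (1.04 ± 0.13) higher, glycolysis 4 of 18 rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.488), and p53 targets 5 of 16 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.267), with Mdm2 (0.99 ± 0.13) higher and Sesn1 (-1.77 ± 0.37) lower. Ear2 lost its call without control 2 (0.0557), range 0.00191 to 0.0557. H2-DMa lost its call without control 1 (0.0615) and 400 µM 3 (0.0606), range 0.00705 to 0.0615. Cxcl3 lost its call without control 1 (0.0597), control 2 (0.0706) and 400 µM 2 (0.129) and without both libraries that stood apart (0.111), range 0.00892 to 0.129.

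Markers of other cell types moved in both directions at 400 µM. The platelet chemokine Ppbp (4.99 ± 1.10) and the smooth muscle actin Acta2 (3.24 ± 0.33) rose, as did the lymphoid genes Cd2 (8.24-fold higher, counting interval 1.83 to 75.8) and Il7r (2.04 ± 0.57) and the fusion gene Dcstamp (2.62 ± 0.48). Gp1bb (-2.78 ± 0.63), Kdr (-1.32 ± 0.39) and Bst2 (-1.59 ± 0.16) fell, and the neutrophil genes Mpo (3.70 ± 1.33) and S100a8 (3.03 ± 1.18) did not pass. By list, neutrophil markers gave 0 of 6 rose and 0 fell (0 and 0 adjusted over the list alone, median -0.06, mean 0.72, test toward higher, adjusted p = 0.910), T and NK cell markers 2 of 3 rose and 0 fell (2 and 0 adjusted over the list alone, adjusted p = 0.298), dendritic cell markers 0 of 7 rose and 1 fell (0 and 1 adjusted over the list alone, adjusted p = 0.184), stromal and endothelial markers 1 of 5 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.364), megakaryocyte and platelet markers 1 of 3 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.983), and osteoclast markers 1 of 8 rose and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.347). B cell, erythroid, and mast cell and basophil markers had 2, 1 and 0 tested genes and were not tested as lists. Replicate 2 at 400 µM stood apart from replicates 1 and 3, with a chi-square per degree of freedom of 62.4 and 49.0 against 10.8 between those 2. Cd2 lost its call without control 1 (0.0565), control 2 (0.0627), control 3 (0.0610) and 400 µM 3 (0.0767), range 0.0213 to 0.0767. Il7r lost its call without control 1 (0.0693), control 3 (0.0715) and 400 µM 2 (0.125), range 0.0111 to 0.125. Kdr lost its call without control 2 (0.0953) and 400 µM 1 (0.0697), 400 µM 3 (0.0930), range 2.57e-04 to 0.0953. Mpo gained a call without 400 µM 3 (0.0361) and with the replicate block (0.00600), range 0.00600 to 0.468.

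**Figure D1:**
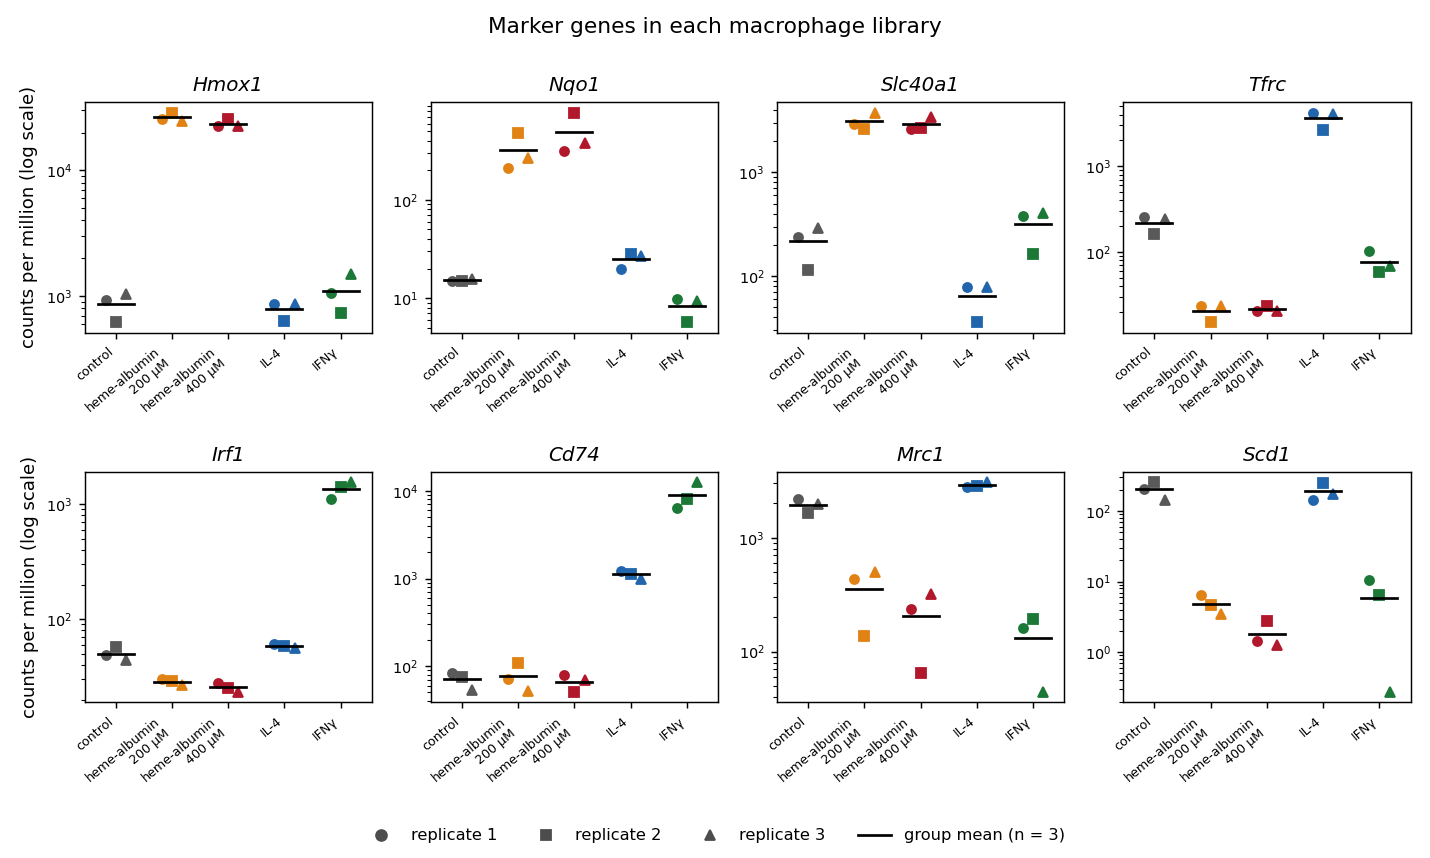
CPM of 8 genes in each of the 15 libraries, on a log axis, with a bar at each group mean. Hmox1, Nqo1 and Slc40a1 stood higher and Tfrc lower in both heme-albumin groups, Irf1 and Cd74 stood highest with IFN-γ, and the mean of Scd1 was lowest at 400 µM.

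Heme-albumin at 200 µM was compared with no treatment as the lower dose. Hmox1 rose by 4.93 ± 0.29 (adjusted p = 2.19e-07) to 26436 ± 2141 CPM and Slc40a1 by 3.85 ± 0.44, while Tfrc (-3.40 ± 0.27) and Scd1 (-5.36 ± 0.68) fell. Slc7a11, Nqo1 and Gclm rose by 4.98 ± 1.05, 4.41 ± 0.40 and 3.30 ± 0.40. In all, 1657 genes rose and 1126 fell, 705 and 346 of them by at least 2-fold. The number higher was 993 without control 1 and 1028 without replicate 2 at 200 µM, and the number lower was 646 without the latter.

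Of the NRF2 targets, 24 of 24 rose and 0 fell (24 and 0 adjusted over the list alone, median 2.11, adjusted p = 2.74e-34, or adjusted p = 0.0295 with an estimated correlation). Aox1 (4.78 ± 0.35), Me1 (2.15 ± 0.18) and Cbr3 (2.19 ± 0.20) were examples. Of the heme and iron handling genes, 12 of 26 rose and 2 fell (12 and 4 adjusted over the list alone, median 0.27, adjusted p = 1.47e-04, or adjusted p = 0.215 with an estimated correlation), with Abcb6 (2.32 ± 0.11) and Spic (4.59 ± 1.02) and the uncertain Fth1 (1.42 ± 0.28) and Ftl1 (1.61 ± 0.22) higher. Of the proteasome subunits, 28 of 31 rose and 1 fell (30 and 1 adjusted over the list alone, median 0.48, adjusted p = 5.47e-14, or adjusted p = 0.0856 with an estimated correlation). Psmb5 (1.29 ± 0.14), Psma5 (1.18 ± 0.10) and Psma7 (0.92 ± 0.08) were higher. Of the glycolysis genes, 6 of 18 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.39, adjusted p = 0.00177, or adjusted p = 0.591 with an estimated correlation). Slc2a1 (1.45 ± 0.14), Pkm (1.11 ± 0.14) and Gpi1 (0.84 ± 0.17) were higher. Of the matrix remodelling genes, 8 of 16 rose and 2 fell (8 and 2 adjusted over the list alone, median 1.21, adjusted p = 1.47e-04, or adjusted p = 0.0690 with an estimated correlation). Mmp8 (3.24 ± 0.33), Mmp19 (2.04 ± 0.13) and Plaur (1.70 ± 0.14) were higher. Of the type I interferon response genes, 0 of 20 rose and 20 fell (0 and 20 adjusted over the list alone, median -2.45, adjusted p = 2.57e-37, or adjusted p = 0.0295 with an estimated correlation). Cmpk2 (-3.16 ± 0.27), Oasl2 (-3.13 ± 0.30) and Stat2 (-1.85 ± 0.13) were lower. Of the interferon-gamma response genes, 2 of 26 rose and 13 fell (2 and 14 adjusted over the list alone, median -1.48 or -1.35 at the bounds, adjusted p = 1.00e-08, or adjusted p = 0.141 with an estimated correlation). Gbp3 (-1.96 ± 0.25) and Irgm1 (-1.41 ± 0.19) were lower. Of the MHC class I presentation genes, 1 of 16 rose and 8 fell (1 and 9 adjusted over the list alone, median -0.35, adjusted p = 0.00221, or adjusted p = 0.606 with an estimated correlation). H2-Q7 (-3.02 ± 0.61), H2-Q4 (-1.10 ± 0.22) and Psmb9 (-0.74 ± 0.17) were lower. The Gbp and H2-Q families have close relatives and are uncertain. Of the cholesterol synthesis genes, 0 of 22 rose and 19 fell (0 and 21 adjusted over the list alone, median -1.59, adjusted p = 2.79e-17, or adjusted p = 0.215 with an estimated correlation). Hmgcs1 (-2.13 ± 0.26), Sc5d (-1.79 ± 0.19) and Nsdhl (-1.77 ± 0.17) were lower. Of the cell cycle genes, 0 of 24 rose and 0 fell (0 and 0 adjusted over the list alone, median -0.67, adjusted p = 0.0376, or adjusted p = 0.832 with an estimated correlation), and Mcm4 (-0.81 ± 0.34), Mcm3 (-0.77 ± 0.37), Mcm6 (-0.67 ± 0.36) and Top2a (-1.03 ± 0.61) did not pass. Mcm4 gained a call with the replicate block (0.0472), range 6.94e-04 to 0.279.

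Large rises were Esam (9.99 ± 0.21), Six4 (at least 57.7-fold higher), Mt3 (373-fold higher, counting interval 66.5 to 14780.1), Adh7 (at least 27.9-fold higher), Hsd11b1 (7.34 ± 0.86), Il1f9 (7.19 ± 1.61) and Ptprn (6.92 ± 0.61). Large falls beside Scd1 were Ifi206 (-4.92 ± 0.61), Cp (28.9-fold lower, counting interval 9.61 to 142), Ifi44 (-4.52 ± 0.47), Iigp1 (-4.35 ± 0.60), Smpd3 (-4.01 ± 0.51), Stab2 (15.3-fold lower, counting interval 3.94 to 131) and Rtp4 (-3.78 ± 0.39). Mrc1 fell (-2.44 ± 0.61), as did H2-Aa (-1.41 ± 0.37) and Irf1 (-0.81 ± 0.13), and Marco (3.28 ± 1.27), Arg1 (-2.35 ± 0.89), Chil3 (-1.47 ± 1.23), Cd40 (-0.55 ± 0.35), Cd86 (-0.10 ± 0.22), H2-Ab1 (-0.53 ± 0.41), Cd74 (0.12 ± 0.29), Ciita (-0.86 ± 0.55), Nos2 (5.10-fold lower, counting interval 1.14 to 46.9), Cxcl9 (at least 5.67-fold lower), Tnf (-0.09 ± 0.12), Il1b (-2.35 ± 1.11) and Il10 (0.76 ± 0.50) did not pass. Retnla had at most 3 counts in either group. The other 21 lists were not called, with a smallest camera adjusted p of 0.114 for dendritic cell markers. The cell cycle list lost its call without control 1 (0.0676), control 2 (0.0659) and 200 µM 2 (0.0968), 200 µM 3 (0.0667) and with DESeq2 size factors, range 2.23e-04 to 0.0968. Integrated stress response gained a camera call without 200 µM 2 (0.0339), range 0.0339 to 0.467. Adh7 lost its call without control 1 (0.115), control 2 (0.109), control 3 (0.0890) and 200 µM 2 (0.168), 200 µM 3 (0.0645), with DESeq2 size factors, with no filter and with upper-quartile factors, range 0.00263 to 0.168. Stab2 lost its call without control 3 (0.0529) and 200 µM 1 (0.0670), 200 µM 2 (0.0538), range 0.00382 to 0.0670. Mrc1 lost its call without 200 µM 2 (0.0504), range 4.66e-04 to 0.0504. H2-Aa lost its call without control 1 (0.0643) and 200 µM 2 (0.0527), 200 µM 3 (0.0574), range 0.00342 to 0.0643. Marco gained a call with the replicate block (0.0280), range 0.0103 to 0.212. Arg1 gained a call with the replicate block (0.0138), range 0.0138 to 0.301. Il1b gained a call with the replicate block (0.0352), range 0.00462 to 0.308. Cd86 changed sign without control 1 (0.05). Cd74 changed sign without control 3 (-0.06) and 200 µM 2 (-0.20). Tnf changed sign without 200 µM 1 (0.00374).

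Both doses were compared with each other to find what the added heme-albumin changed. No gene passed with edgeR, where the smallest adjusted p was 0.291 and 1796 genes had an unadjusted p under 0.05. DESeq2 called 3 higher and 10 lower, with 1834 at an unadjusted p under 0.05. A fit of these 6 libraries alone with the replicate number as a block, added after the results were seen, called 146 higher and 90 lower, while the same block in the fit of all 15 libraries called 0 (smallest adjusted p 0.0719). LXR targets lay lower at 400 µM as a group (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895 for Abca1). Hmox1 did not differ past the threshold (-0.17 ± 0.24), nor did Slc7a11 (0.91 ± 0.85), Nqo1 (0.61 ± 0.34), Gclm (0.28 ± 0.36), Marco (-0.62 ± 1.17) and Mrc1 (-0.79 ± 0.59) or the other reported marker genes.

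Of the LXR targets, 0 of 13 rose and 0 fell (0 and 3 adjusted over the list alone, median -0.80, adjusted p = 1.13e-05, or adjusted p = 0.0132 with an estimated correlation). The members were led by Pltp (-1.42 ± 0.43), Abca1 (-1.32 ± 0.29), Srebf1 (-0.80 ± 0.23) and Abcg1 (-0.80 ± 0.32), and Abca1 stood at 105 ± 24.4, 69.8 ± 11.4 and 27.9 ± 4.33 CPM at 0, 200 and 400 µM. This was the only list of the 31 called in this comparison with both correlations, and its camera adjusted p ranged from 2.96e-15 to 0.00334 over 12 other settings. Among type I interferon genes, 0 of 20 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.41, adjusted p = 2.41e-06, or adjusted p = 0.886 with an estimated correlation). Oasl2 (1.21 ± 0.29) and Oas2 (1.10 ± 0.30) led it. Of the glycolysis genes, 0 of 18 rose and 0 fell (0 and 1 adjusted over the list alone, median -0.32, adjusted p = 1.13e-05, or adjusted p = 0.886 with an estimated correlation). Slc2a1 (-0.54 ± 0.14) and Pfkl (-0.91 ± 0.29) led it. Of the proteasome subunits, 0 of 31 rose and 0 fell (0 and 0 adjusted over the list alone, median -0.10, adjusted p = 0.00126, or adjusted p = 0.886 with an estimated correlation). Psmd4 (-0.33 ± 0.08) and Psma7 (-0.27 ± 0.08) led it. Of the core macrophage genes, 0 of 14 rose and 0 fell (0 and 0 adjusted over the list alone, median -0.34, adjusted p = 0.00983, or adjusted p = 0.886 with an estimated correlation). Spi1 (-0.54 ± 0.19) and Cx3cr1 (-0.95 ± 0.38) led it. Of the anti-inflammatory mediators, 0 of 16 rose and 0 fell (0 and 1 adjusted over the list alone, median -0.26, adjusted p = 0.0472, or adjusted p = 0.886 with an estimated correlation). Tgfb1 (-0.52 ± 0.13) and Sbno2 (-0.43 ± 0.18) led it. None of these genes passed over all genes. Without replicate 2 at 400 µM, the median was -0.0631 for the proteasome and -0.207 for core macrophage genes. Leaving out replicate 2 at 200 µM gave 10 called lists in place of 6. The other 25 lists were not called, with a smallest camera adjusted p of 0.109 for the lysosome. The anti-inflammatory mediators list lost its call without 200 µM 2 (0.415) and 400 µM 1 (0.116), 400 µM 3 (0.0617) and with a 5 CPM filter, range 0.00254 to 0.415. Cholesterol synthesis gained a camera call without 200 µM 1 (1.17e-06) and 400 µM 2 (1.39e-06), range 3.77e-07 to 0.968. NRF2 antioxidant targets gained a camera call without 200 µM 2 (0.0140), range 0.0140 to 0.981. Tissue macrophage identity gained a camera call without 200 µM 2 (0.0470), range 0.0470 to 0.995. Lysosome gained a camera call without 200 µM 2 (0.0162) and 400 µM 1 (0.00935), range 0.00935 to 0.947. Integrated stress response gained a camera call without 200 µM 2 (0.00296) and 400 µM 3 (0.00841), range 0.00296 to 0.904. Unfolded protein response gained a camera call without 200 µM 2 (0.0350), range 0.0350 to 0.947. Without 400 µM 2, cholesterol synthesis had an adjusted p of 0.850 with an estimated correlation.

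**Figure D2:**
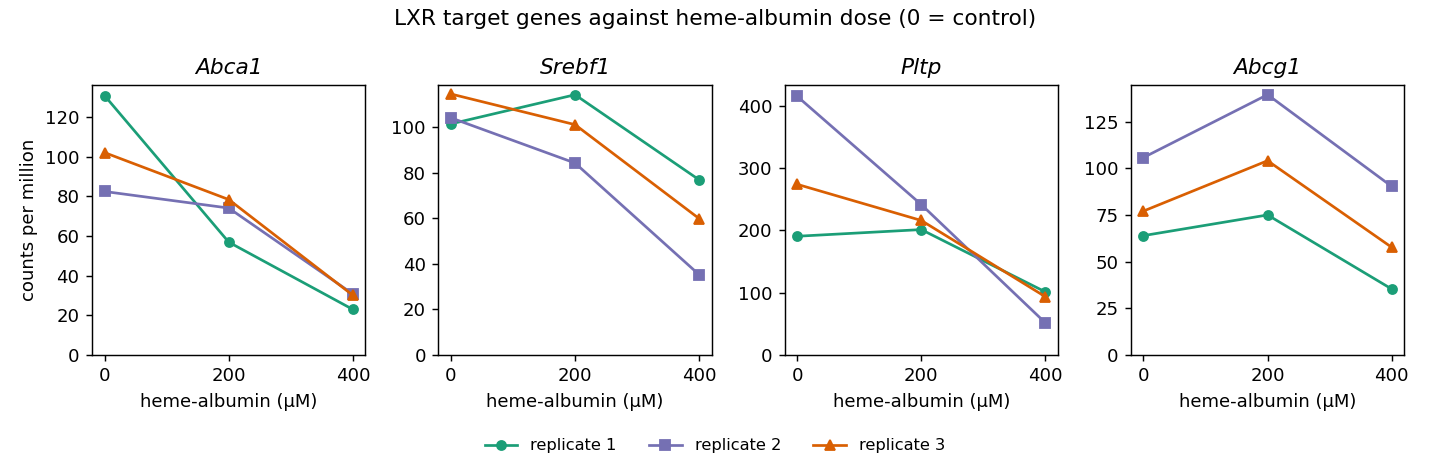
CPM of 4 LXR target genes against the heme-albumin dose (0, 200 and 400 µM), with a line joining the libraries of each replicate number. Mean levels of Abca1 were 105.2, 69.8 and 27.9 CPM at the 3 doses.

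IL-4 was compared with no treatment as M2 polarization. Arg1, which degrades arginine (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), rose by 11.37 ± 0.62 (adjusted p = 1.04e-07), from 1.28 ± 0.886 to 3553 ± 529.7 CPM. Retnla was 90935-fold higher, counting interval 16321 to 3591760, and Chil3, a chitinase-like protein, rose by 11.28 ± 1.16. Tnf (-3.71 ± 0.13) and Marco (-7.52 ± 1.66) fell. In all, 1764 genes rose and 1415 fell, 701 and 614 of them by at least 2-fold.

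Of the IL-4 response genes, 24 of 27 rose and 1 fell (24 and 1 adjusted over the list alone, median 4.75, adjusted p = 4.95e-40, or adjusted p = 6.79e-05 with an estimated correlation). Mgl2 (7.89 ± 0.51), Cdh1 (7.83 ± 0.31) and Cish (6.20 ± 0.37) were higher. Of the MHC class II presentation genes, 8 of 11 rose and 0 fell (9 and 0 adjusted over the list alone, median 2.52, adjusted p = 8.48e-12, or adjusted p = 0.0291 with an estimated correlation). Ciita (4.53 ± 0.33), H2-DMa (2.52 ± 0.20) and H2-DMb1 (1.57 ± 0.12) were higher. Of the osteoclast markers, 6 of 8 rose and 0 fell (6 and 0 adjusted over the list alone, median 3.84, adjusted p = 1.07e-05, or adjusted p = 0.0291 with an estimated correlation). Atp6v0d2 (5.48 ± 0.68), Acp5 (4.08 ± 0.47) and Itgb3 (4.01 ± 0.27) were higher. Of the lysosome genes, 11 of 25 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.32, adjusted p = 2.65e-04, or adjusted p = 0.541 with an estimated correlation). Tfeb (1.94 ± 0.29), Tfec (1.29 ± 0.19) and Ctsl (1.15 ± 0.14) were higher. Of the matrix remodelling genes, 7 of 16 rose and 4 fell (8 and 5 adjusted over the list alone, median -0.13, mean 0.55, test toward higher, adjusted p = 0.0289, or adjusted p = 0.218 with an estimated correlation). Fn1 (10.10 ± 0.87), Mmp19 (1.97 ± 0.13) and Plaur (1.86 ± 0.14) were higher. Of the type I interferon response genes, 0 of 20 rose and 19 fell (0 and 19 adjusted over the list alone, median -3.32, adjusted p = 1.43e-36, or adjusted p = 0.0170 with an estimated correlation). Ifit3 (-4.89 ± 0.40), Rsad2 (-4.10 ± 0.29) and Isg15 (-2.76 ± 0.24) were lower. Of the interferon-gamma response genes, 1 of 26 rose and 14 fell (2 and 14 adjusted over the list alone, median -1.55 or -1.46 at the bounds, adjusted p = 2.26e-09, or adjusted p = 0.0967 with an estimated correlation), with Acod1 (-5.32 ± 0.50), Cxcl10 (-5.25 ± 0.49) and Fcgr1 (-4.08 ± 0.28) lower and Socs1, an inhibitor of cytokine signalling, higher (5.56 ± 0.47). Of the inflammatory cytokines, 1 of 19 rose and 10 fell (2 and 11 adjusted over the list alone, median -1.33, adjusted p = 9.28e-10, or adjusted p = 0.00465 with an estimated correlation). Nfkbiz (-2.85 ± 0.22), Ccl4 (-2.61 ± 0.25) and Nlrp3 (-2.15 ± 0.13) were lower. Of the tissue macrophage identity genes, 0 of 15 rose and 7 fell (0 and 8 adjusted over the list alone, median -1.60, adjusted p = 0.00898, or adjusted p = 0.541 with an estimated correlation). Hpgd (-3.01 ± 0.46), Slc40a1 (-1.74 ± 0.40) and Folr2 (-1.60 ± 0.42) were lower. Of the glycolysis genes, 0 of 18 rose and 4 fell (0 and 4 adjusted over the list alone, median -0.23, adjusted p = 0.0493, or adjusted p = 0.690 with an estimated correlation). Aldoc (-2.33 ± 0.43), Pdk1 (-1.29 ± 0.23) and Pgk1 (-1.01 ± 0.18) were lower. Folr2 lost its call without IL-4 2 (0.0539), range 8.17e-05 to 0.0539.

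Large rises beside Retnla were Rnase2a (19277-fold higher, counting interval 5336 to 159179), Msx3 (at least 1518-fold higher), Cldn11 (at least 1190.5-fold higher), Chil4 (at least 1066-fold higher), Tuba8 (at least 999.8-fold higher), Scn3a (at least 570.0-fold higher) and Kcnd3 (at least 387-fold higher). Large falls beside Marco were Ly6a (-6.72 ± 0.69), Ifit3b (131-fold lower, counting interval 35.8 to 1092), Cx3cr1 (-6.65 ± 0.55), Gpr84 (-6.53 ± 0.74), Fpr2 (-6.35 ± 1.08), Saa3 (-6.20 ± 1.35) and Sncaip (-6.11 ± 0.51). Chil3 and Chil4, Ifit3 and Ifit3b, and Rnase2a belong to families of close relatives and are uncertain. Of the markers, Cd86 (-0.81 ± 0.22) and Il10 (-2.07 ± 0.56) fell and H2-Aa (3.25 ± 0.36), H2-Ab1 (3.77 ± 0.41), Cd74 (3.97 ± 0.32) and Ftl1 (0.75 ± 0.22) rose, while Mrc1 (0.58 ± 0.58), Hmox1 (-0.14 ± 0.24), Slc7a11 (1.15 ± 0.99), Nqo1 (0.71 ± 0.36), Gclm (-0.43 ± 0.37), Fth1 (-0.22 ± 0.28), Spic (-0.88 ± 1.35), Cd40 (0.48 ± 0.34), Irf1 (0.23 ± 0.13) and Il1b (-2.41 ± 0.98) did not pass. Nos2 was 9.26-fold lower, counting interval 2.06 to 85.2 and Cxcl9 30.9-fold lower, counting interval 4.94 to 1279, and neither passed. The other 21 lists were not called, with a smallest camera adjusted p of 0.0651 for heat shock genes. The extracellular matrix remodelling list lost its call without control 2 (0.0600), with no filter, with a 5 CPM filter, with the replicate block (0.0723) and without both libraries that stood apart (0.0899), range 0.00789 to 0.151. The glycolysis list lost its call without control 2 (0.0600) and IL-4 1 (0.0559), IL-4 3 (0.0998), with a 5 CPM filter and with the replicate block (0.0789), range 0.00789 to 0.0998. MHC class I presentation gained a camera call without control 1 (0.0291), control 3 (0.0408), range 0.0223 to 0.2001. Heat shock response gained a camera call without control 1 (0.0397), control 2 (0.0481), range 0.0272 to 0.164. Core macrophage genes gained a camera call without control 1 (0.0360), range 0.0360 to 0.19996. Cd86 lost its call without control 1 (0.0776) and IL-4 2 (0.0585), range 0.00278 to 0.0776. Il10 lost its call without IL-4 2 (0.0564), range 2.84e-04 to 0.0564. Ftl1 lost its call without control 1 (0.0856), control 2 (0.0553), control 3 (0.0558) and IL-4 1 (0.0523), IL-4 2 (0.0594), range 1.48e-04 to 0.0856. Il1b gained a call with the replicate block (0.01005), range 0.00125 to 0.193. Cxcl9 gained a call with the replicate block (0.0402), range 0.00472 to 0.525.

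IFN-γ was compared with no treatment as M1 polarization. Irf1 rose by 4.76 ± 0.15 (adjusted p = 2.15e-10). Nos2, which makes nitric oxide (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), rose by 9.76 ± 0.96, from 0.260 ± 0.247 to 257 ± 256 CPM. The MHC class II regulator Ciita rose by 8.19 ± 0.34, and Cd74 by 6.99 ± 0.37, from 70.8 ± 15.1 to 9026 ± 3172 CPM. In all, 2857 genes rose and 2308 fell, 1175 and 878 of them by at least 2-fold.

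Of the interferon-gamma response genes, 26 of 26 rose and 0 fell (26 and 0 adjusted over the list alone, median 7.13 or 6.601 at the bounds, adjusted p = 3.07e-83, or adjusted p = 1.57e-04 with an estimated correlation). Gbp8 (7.97 ± 0.26) and Gbp3 (6.29 ± 0.24) were higher. Among MHC class II presentation genes, 11 of 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 5.61, adjusted p = 4.80e-28, or adjusted p = 0.00394 with an estimated correlation). H2-Aa (7.03 ± 0.43), H2-DMa (4.86 ± 0.22) and H2-DMb1 (3.48 ± 0.13) were higher. Among MHC class I presentation genes, 16 of 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 2.22, adjusted p = 2.37e-30, or adjusted p = 0.0103 with an estimated correlation). Tap1 (3.20 ± 0.18), Nlrc5 (2.95 ± 0.13) and Psme2 (1.68 ± 0.09) were higher. Of the type I interferon response genes, 19 of 20 rose and 0 fell (19 and 0 adjusted over the list alone, median 2.12, adjusted p = 3.80e-16, or adjusted p = 0.0725 with an estimated correlation). Ifi44 (5.35 ± 0.27), Ifit2 (4.14 ± 0.30) and Mx1 (3.82 ± 0.28) were higher. Of the costimulatory and checkpoint ligands, 8 of 14 rose and 1 fell (8 and 1 adjusted over the list alone, median 1.15, adjusted p = 0.00333, or adjusted p = 0.0412 with an estimated correlation). Cd274 (6.10 ± 0.55), Cd86 (3.95 ± 0.22) and Icam1 (1.65 ± 0.22) were higher. Of the anti-inflammatory mediators, 11 of 16 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.31, adjusted p = 0.00101, or adjusted p = 0.417 with an estimated correlation). Il18bp (6.28 ± 0.33), Socs3 (3.85 ± 0.41) and Sbno2 (1.29 ± 0.18) were higher. Of the glycolysis genes, 6 of 18 rose and 1 fell (6 and 0 adjusted over the list alone, median 0.37, adjusted p = 0.0235, or adjusted p = 0.647 with an estimated correlation). Pfkfb3 (3.10 ± 0.20), Hk2 (1.57 ± 0.14) and Hk1 (1.23 ± 0.15) were higher. Of the cholesterol synthesis genes, 0 of 22 rose and 22 fell (0 and 22 adjusted over the list alone, median -2.39, adjusted p = 7.45e-17, or adjusted p = 0.286 with an estimated correlation). Sc5d (-2.26 ± 0.19), Msmo1 (-2.25 ± 0.23) and Nsdhl (-1.93 ± 0.17) were lower. Of the unfolded protein response genes, 0 of 17 rose and 6 fell (0 and 6 adjusted over the list alone, median -0.49, adjusted p = 0.0201, or adjusted p = 0.726 with an estimated correlation). Herpud1 (-1.41 ± 0.30) and Sdf2l1 (-1.02 ± 0.26) were lower. Of the cell cycle genes, 0 of 24 rose and 18 fell (0 and 19 adjusted over the list alone, median -1.505, adjusted p = 5.07e-05, or adjusted p = 0.647 with an estimated correlation). Mcm6 (-1.63 ± 0.37), Mcm4 (-1.31 ± 0.34) and E2f1 (-0.80 ± 0.17) were lower. The cell cycle median was 6.25, 5.50 and 3.26 log2 CPM in IFN-γ replicates 1, 2 and 3. Mcm4 lost its call with 6 libraries, range 6.08e-04 to 0.0579.

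Large rises were Gbp2b (32118-fold higher, counting interval 5764 to 1268620), Gbp10 (at least 1799.8-fold higher), Gbp11 (at least 1147-fold higher), Serpina3g (13.04 ± 0.48), Serpina3f (8570.1-fold higher, counting interval 2372 to 70771), Tlr12 (at least 607-fold higher), Gbp4 (12.08 ± 0.44) and Ocstamp (3461-fold higher, counting interval 958 to 28582). The guanylate-binding proteins and the Serpina3 genes have close relatives and are uncertain. Large falls were Tox2 (-8.10 ± 0.45), Cbr2 (-7.88 ± 0.82), Nptx1 (77.6-fold lower, counting interval 21.01 to 648), Cmah (-5.90 ± 0.72), Col23a1 (67.8-fold lower, counting interval 18.3 to 567), Fbln5 (58.0-fold lower, counting interval 15.6 to 487), Nes (-5.49 ± 0.52) and Rasgrp3 (-5.47 ± 0.55). Of the markers, H2-Ab1 (7.44 ± 0.48), Arg1 (6.01 ± 0.53), Cxcl9 (8.90 ± 1.15), Cd40 (1.39 ± 0.34), Tnf (0.65 ± 0.12), Il1b (3.24 ± 0.69), Il10 (1.32 ± 0.49), Slc7a11 (2.72 ± 0.99) and Spic (2.87 ± 1.04) rose and Mrc1 (-3.86 ± 0.65) fell, while Hmox1 (0.34 ± 0.24), Nqo1 (-0.88 ± 0.38), Gclm (0.78 ± 0.37), Fth1 (0.35 ± 0.28), Ftl1 (0.32 ± 0.22), Slc40a1 (0.55 ± 0.39), Marco (-0.39 ± 1.17), Chil3 (1.29 ± 0.94) and Retnla (43.7-fold higher, counting interval 7.54 to 1756) did not pass. Replicate 3 stood apart from replicates 1 and 2, with a chi-square per degree of freedom of 135 and 130.4 against 44.7 between those 2. The other 21 lists were not called, with a smallest camera adjusted p of 0.0681 for inflammatory cytokines. The glycolysis list lost its call without IFN-γ 1 (0.0975), IFN-γ 2 (0.0685), range 2.44e-04 to 0.0975. The unfolded protein response list lost its call without IFN-γ 3 (0.0822) and without both libraries that stood apart (0.0649), range 7.24e-04 to 0.0822. IL-4 response gained a camera call without IFN-γ 3 (0.0133), range 0.0112 to 0.115. Inflammatory cytokines and chemokines gained a camera call without control 1 (0.0451), range 0.0280 to 0.0904. Integrated stress response gained a camera call without IFN-γ 3 (0.0186), range 0.00646 to 0.183. The p53 targets and cell death gained a camera call without control 3 (0.0467), range 0.0162 to 0.123. Dendritic cell markers gained a camera call without IFN-γ 3 (0.0293), range 0.0293 to 0.551. Il10 lost its call without control 1 (0.0924), control 2 (0.137), control 3 (0.0762) and IFN-γ 1 (0.0980), IFN-γ 2 (0.157), with no filter, with 6 libraries and with upper-quartile factors, range 4.83e-04 to 0.157. Slc7a11 lost its call without control 1 (0.0772), control 2 (0.129), control 3 (0.0954) and IFN-γ 3 (0.407), without both libraries that stood apart (0.364), with no filter, with 6 libraries, with the replicate block (0.0775) and with upper-quartile factors, range 0.00914 to 0.407. Spic lost its call without control 1 (0.0684), control 2 (0.130), control 3 (0.0911) and IFN-γ 3 (0.738), without both libraries that stood apart (0.739), with no filter, with 6 libraries and with the replicate block (0.0648), range 0.00401 to 0.739. Gclm gained a call without IFN-γ 2 (0.0134), range 0.0134 to 0.944. Ftl1 gained a call without IFN-γ 1 (0.0271), range 0.0271 to 0.955. Fth1 changed sign without IFN-γ 3 (-0.07). Marco changed sign without control 1 (0.28) and IFN-γ 1 (0.03), IFN-γ 2 (0.19). Chil3 changed sign without IFN-γ 3 (-0.53). Retnla changed sign without IFN-γ 3 (-1.96).

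**Figure D3:**
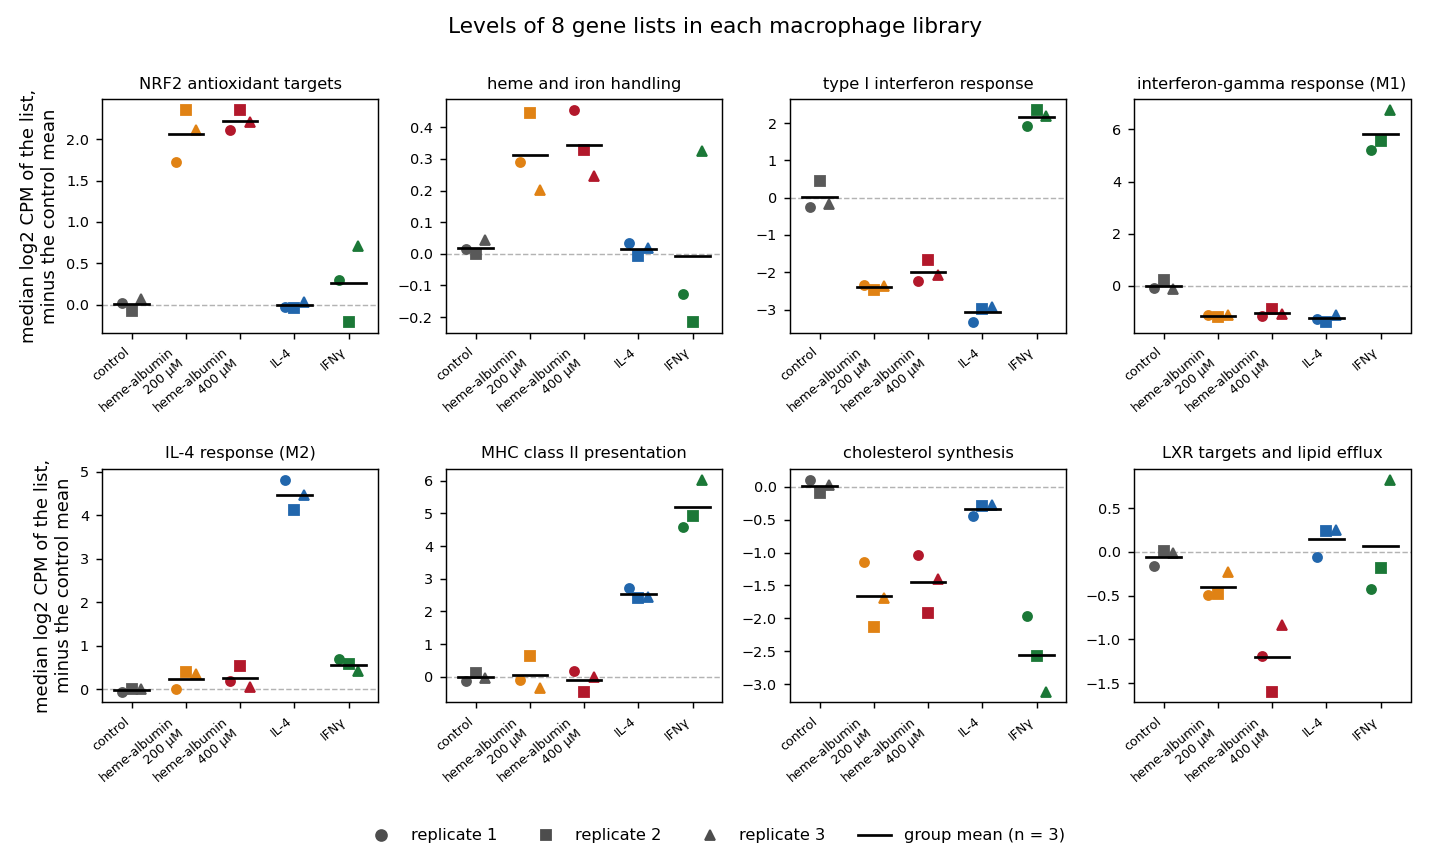
Levels of 8 fixed gene lists in each library, as the median over a list's members of log2 CPM less that member's own mean in the 3 controls. NRF2 targets stood highest in the heme-albumin libraries, interferon-gamma response and MHC class II genes with IFN-γ (the latter above the controls with IL-4 too), and IL-4 response genes with IL-4.

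Heme-albumin at 400 µM was compared directly with IL-4. Hmox1 stood higher with heme by 4.90 ± 0.29 (adjusted p = 4.85e-08), Nqo1 by 4.30 ± 0.40 and Slc40a1 by 5.49 ± 0.47. Arg1 was 104010-fold lower, counting interval 18668 to 4108210 with heme and Chil3 fell (-11.60 ± 1.20). In all, 2427 genes rose and 2352 fell, 1154 and 798 of them by at least 2-fold. Large rises were Esam (10.90 ± 0.21), Marco (10.17 ± 1.80), Rnf183 (914-fold higher, counting interval 312 to 4439) and Ptpn14 (at least 120.1-fold higher), and large falls beside Arg1 were Retnla (at least 22069.6-fold lower), Msx3 (at least 1105-fold lower), Rnase2a (14035-fold lower, counting interval 3885 to 115897) and Chil4 (at least 776-fold lower). Markers higher with heme were Spic (5.80 ± 1.05), Tnf (3.63 ± 0.13), Il10 (2.58 ± 0.56), Slc7a11 (4.73 ± 1.00), Gclm (4.00 ± 0.41), Fth1 (1.86 ± 0.29) and Cd86 (1.17 ± 0.22), and those lower were Cd74 (-4.06 ± 0.32), Ciita (-6.06 ± 0.42), H2-Aa (-5.00 ± 0.41), H2-Ab1 (-4.47 ± 0.44), Mrc1 (-3.80 ± 0.65), Cd40 (-1.84 ± 0.36) and Irf1 (-1.21 ± 0.13). Ftl1 (0.51 ± 0.22) and Il1b (0.25 ± 1.38) did not pass, and Nos2 and Cxcl9 had at most 3 counts in either group. Ptpn14 lost its call without 400 µM 2 (0.0630) and without both libraries that stood apart (0.0516), range 0.00801 to 0.0630. Il1b changed sign without 400 µM 3 (-0.84) and IL-4 2 (-0.02).

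Against IL-4, of the NRF2 targets 20 of 24 rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p = 2.09e-19, or adjusted p = 0.0942 with an estimated correlation). Of the inflammatory cytokines 12 of 19 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 3.11e-06, or adjusted p = 0.0194 with an estimated correlation). Among type I interferon genes 12 of 20 rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 0.00495, or adjusted p = 0.627 with an estimated correlation). Of the tissue macrophage identity genes 8 of 15 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0380, or adjusted p = 0.627 with an estimated correlation). Of the proteasome subunits 17 of 31 rose and 2 fell (17 and 2 adjusted over the list alone, adjusted p = 0.00245, or adjusted p = 0.627 with an estimated correlation). Of the glycolysis genes 9 of 18 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 0.0185, or adjusted p = 0.627 with an estimated correlation). Of the IL-4 response genes 2 of 27 rose and 25 fell (2 and 25 adjusted over the list alone, adjusted p = 3.27e-23, or adjusted p = 5.68e-04 with an estimated correlation). Of the MHC class II genes 0 of 11 rose and 8 fell (2 and 8 adjusted over the list alone, adjusted p = 2.39e-08, or adjusted p = 0.0942 with an estimated correlation). Of the osteoclast markers 0 of 8 rose and 5 fell (0 and 5 adjusted over the list alone, adjusted p = 0.00457, or adjusted p = 0.218 with an estimated correlation). Of the cholesterol synthesis genes 0 of 22 rose and 13 fell (0 and 14 adjusted over the list alone, adjusted p = 4.95e-05, or adjusted p = 0.627 with an estimated correlation). Of the LXR targets 1 of 13 rose and 7 fell (2 and 7 adjusted over the list alone, adjusted p = 0.0215, or adjusted p = 0.118 with an estimated correlation). Of the lysosome genes 1 of 25 rose and 13 fell (2 and 14 adjusted over the list alone, adjusted p = 0.00457, or adjusted p = 0.627 with an estimated correlation). Of the unfolded protein response genes 1 of 17 rose and 9 fell (1 and 10 adjusted over the list alone, adjusted p = 0.0165, or adjusted p = 0.750 with an estimated correlation). The other 18 lists were not called, with a smallest camera adjusted p of 0.0872 for heme and iron handling. The glycolysis list lost its call without 400 µM 1 (0.0648), range 5.48e-04 to 0.0648. The tissue macrophage identity list lost its call without 400 µM 3 (0.0680) and IL-4 2 (0.0536), range 0.00264 to 0.0680. Integrated stress response gained a camera call without 400 µM 2 (0.0136), range 0.00329 to 0.311. Core macrophage genes gained a camera call without 400 µM 2 (0.0408), range 0.0335 to 0.472.

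Heme-albumin at 400 µM was also compared directly with IFN-γ. Hmox1 stood higher with heme by 4.43 ± 0.28 (adjusted p = 3.67e-08), Nqo1 by 5.90 ± 0.43 and Slc40a1 by 3.19 ± 0.42. Interferon and antigen presentation genes stood lower, among them Ciita (-9.71 ± 0.40) and Cd74 (-7.08 ± 0.37). In all, 2439 genes rose and 2645 fell, 1046 and 1035 of them by at least 2-fold. Large rises were Mt3 (at least 202-fold higher), Esam (10.18 ± 0.20), Ceacam10 (at least 142-fold higher), Rassf6 (at least 84.8-fold higher) and Hunk (at least 63.9-fold higher), and large falls Gbp2b (at least 7795-fold lower), Serpina3f (at least 4159.9-fold lower), Tgtp1 (at least 4003-fold lower), Iigp1 (49444-fold lower, counting interval 8874 to 1952960) and Nos2 (at least 2267-fold lower), of which the first 4 have close relatives and are uncertain. Of the markers, Slc7a11 (3.17 ± 0.92), Gclm (2.80 ± 0.39), Fth1 (1.29 ± 0.28) and Ftl1 (0.95 ± 0.22) rose, Arg1 (2669-fold lower, counting interval 479 to 105438), Cxcl9 (at least 2036-fold lower), H2-Aa (-8.77 ± 0.47), H2-Ab1 (-8.15 ± 0.50), Irf1 (-5.73 ± 0.16), Cd86 (-3.59 ± 0.22), Cd40 (-2.75 ± 0.37), Tnf (-0.72 ± 0.12) and Il1b (-5.40 ± 0.91) fell, and Marco (3.04 ± 1.26), Spic (2.05 ± 0.81), Mrc1 (0.64 ± 0.59), Chil3 (-1.61 ± 1.02), Retnla (at least 10.6-fold lower) and Il10 (-0.82 ± 0.48) did not pass. Slc7a11 lost its call without 400 µM 2 (0.0611) and with 6 libraries, range 8.57e-04 to 0.0893. Fth1 lost its call with 6 libraries, range 7.14e-06 to 0.0535. Ftl1 lost its call with 6 libraries, range 1.01e-04 to 0.0586. Marco gained a call without 400 µM 2 (0.0441) and IFN-γ 3 (0.00436) and with the replicate block (0.0235), range 0.00167 to 0.229. Spic gained a call without IFN-γ 3 (4.90e-06) and with the replicate block (0.0152), range 4.90e-06 to 0.232. Chil3 gained a call without IFN-γ 2 (0.0486), range 0.0486 to 0.890. Il10 gained a call without IFN-γ 3 (0.0214), range 0.0214 to 0.506. Chil3 changed sign without IFN-γ 3 (0.20).

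Against IFN-γ, of the NRF2 targets 22 of 24 rose and 0 fell (22 and 0 adjusted over the list alone, adjusted p = 4.48e-14, or adjusted p = 0.102 with an estimated correlation). Of the heme and iron handling genes 11 of 26 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 0.00449, or adjusted p = 0.299 with an estimated correlation). Of the cholesterol synthesis genes 12 of 22 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 0.00449, or adjusted p = 0.622 with an estimated correlation). Of the proteasome subunits 17 of 31 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 0.0122, or adjusted p = 0.475 with an estimated correlation). Of the matrix remodelling genes 9 of 16 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 8.77e-04, or adjusted p = 0.0539 with an estimated correlation). Of the interferon-gamma response genes 0 of 26 rose and 26 fell (0 and 26 adjusted over the list alone, adjusted p = 4.32e-83, or adjusted p = 3.18e-04 with an estimated correlation). Among type I interferon genes 0 of 20 rose and 20 fell (0 and 20 adjusted over the list alone, adjusted p = 7.07e-36, or adjusted p = 0.0121 with an estimated correlation). Among MHC class I genes 0 of 16 rose and 16 fell (0 and 16 adjusted over the list alone, adjusted p = 7.79e-36, or adjusted p = 0.00933 with an estimated correlation). Among MHC class II genes 0 of 11 rose and 11 fell (0 and 11 adjusted over the list alone, adjusted p = 6.34e-24, or adjusted p = 0.00579 with an estimated correlation). Of the costimulatory and checkpoint ligands 2 of 14 rose and 8 fell (2 and 9 adjusted over the list alone, adjusted p = 0.00449, or adjusted p = 0.0421 with an estimated correlation). Of the anti-inflammatory mediators 0 of 16 rose and 10 fell (0 and 11 adjusted over the list alone, adjusted p = 8.77e-04, or adjusted p = 0.352 with an estimated correlation). The other 20 lists were not called, with a smallest camera adjusted p of 0.0610 for inflammatory cytokines. Inflammatory cytokines and chemokines gained a camera call without 400 µM 3 (0.0368) and IFN-γ 3 (0.0232), range 0.0176 to 0.119. Phagocytic and scavenger receptors gained a camera call without 400 µM 3 (0.0443), range 0.0368 to 0.121. Integrated stress response gained a camera call without 400 µM 2 (0.00508) and IFN-γ 3 (0.0164), range 4.51e-04 to 0.126. Dendritic cell markers gained a camera call without 400 µM 2 (0.0483), 400 µM 3 (0.0377) and IFN-γ 2 (0.0394), IFN-γ 3 (0.00385) and with the replicate block (0.0253), range 0.00385 to 0.0575. LXR targets and lipid efflux gained a camera call without IFN-γ 3 (0.0170), range 0.0166 to 0.118. Cell cycle gained a camera call without 400 µM 2 (0.0165) and IFN-γ 1 (8.16e-04), range 8.16e-04 to 0.434. Glycolysis gained a camera call without IFN-γ 3 (0.0170), range 0.0170 to 0.260.

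Changes against the shared controls were compared between treatments. The heme doses called 1979 genes the same way (1173 higher and 806 lower, against 243 and 121 for independent lists) and 0 opposite ways, although a direct test between them called none with edgeR (1796 at an unadjusted p under 0.05, and 13 with DESeq2). The 400 µM dose and IL-4 called 760 genes the same way (392 higher and 368 lower, against 258 and 152) and 351 opposite ways (216 higher and 135 lower at 400 µM, against 207 and 189.6). The 400 µM dose and IFN-γ called 1181 the same way (641 higher and 540 lower, against 418 and 248) and 480 opposite ways (230 and 250, against 338 and 307). Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.909, 0.211 and 0.161, and Spearman's rho 0.792, 0.196 and 0.290. Unchanged groups simulated against the same controls gave r of 0.485, 0.500 and 0.491 and 0 called genes. The covariance was 0.788, 0.227 and 0.197, against 0.0375, 0.0374 and 0.0368 in the simulation. Without controls 1, 2 and 3 in turn, the opposite calls of the 400 µM dose and IL-4 numbered 212, 206 and 221, and the same-way calls of that dose and IFN-γ 741, 766 and 775. Without control 1 the same-way calls of that dose and IL-4 numbered 493. The 3 controls cannot be split into parts of 2 each, so part of each excess may come from them.

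Groups did not overlap in CPM for 5397 of the tested genes at 400 µM against control (45.4%), 6157 at 200 µM (51.8%), 2670 between the doses (22.5%), 6535 with IL-4 (55.0%) and 6162 with IFN-γ (51.9%), where chance gives 10%. Directly against IL-4 the number was 6664 (56.1%), and against IFN-γ 5177 (43.6%).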

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

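The alternatives without the libraries that stood apart (400 µM 2 and IFN-γ 3) and with the block on 6 libraries were chosen after the results were seen. Of 851 gene results, each under its alternatives (11771 values), 11216 values kept their direction and side of the threshold, 322 lost a call, 152 gained one and 81 changed sign, in 47 results. None of the 47 was called with the settings as fixed or in the setting that turned it, and the largest reached 2.76 on the log2 scale. Of 70 list calls, 61 were kept in every one of their 12 settings and 0 turned, and 30 other list results were called in some setting (75 values, 0 turned). No cause of a change below was tested.

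Camera with an estimated correlation called 2 lists at 400 µM, 2 at 200 µM, 1 between the doses, 5 with IL-4, 4 with IFN-γ, 2 for 400 µM against IL-4 and 5 against IFN-γ. Fry called 18 at 400 µM, 1 between the doses, 19 with IFN-γ and 24 for 400 µM against IFN-γ. Between the doses, leaving out 1 library gave 6 to 10 lists. DESeq2 called 3 genes higher and 10 lower between the doses, 1 and 3 by at least 2-fold. With only the 6 libraries compared, 2155 genes were lower at 200 µM, 2511 lower with IL-4, and 1265 higher and 1477 lower for 400 µM against IFN-γ. With that and the replicate block, the counts higher and lower were 2575 and 2475 at 200 µM, 146 and 90 between the doses (52 and 23 by at least 2-fold), 3320 and 3266 with IL-4, and 978 and 1101 for 400 µM against IFN-γ. Without both libraries that stood apart, 1956 genes were lower at 200 µM, 1 lower between the doses (1 by at least 2-fold), 2173 lower with IL-4, and 558 were called opposite ways at 400 µM and with IL-4. Leaving out 1 library gave 993 to 1388 genes higher and 646 to 926 lower at 200 µM, 493 to 703 called the same way and 206 to 359 opposite ways at 400 µM and with IL-4, and 741 to 1408 the same way at 400 µM and with IFN-γ. The replicate block in the fit of all 15 libraries moved no count of calls by over 1.5 times: of 3017, 2783, 3179 and 5165 genes called at 400 µM, at 200 µM, with IL-4 and with IFN-γ, it kept 2960, 2726, 3111 and 5089. Without both libraries that stood apart, LXR targets at 200 µM (0.00164), the unfolded protein response with IL-4 (0.0163) and heme and iron handling for 400 µM against IL-4 (0.00809) gained a camera call.

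Fold changes that turned sign are given as log2 values under the setting. Without both libraries that stood apart, Atp6v0d2 -0.24, Cxcl3 -0.45, Fth1 -0.0998, Gp1bb 0.12, Il10 0.0736, Itgax -0.0948, Kdr -0.0757, Mcm5 0.00818, Mmp12 -0.0871 and S100a8 -0.0255 (between doses), Cd74 0.0776, Chil3 0.0110 and Cxcl12 -0.0703 (400 µM), Chil3 0.57 (400 µM against IFN-γ) and Chil3 -0.56, Fth1 -0.0736 and Retnla -2.00 (IFN-γ). Without the low-count filter, Cd2 -0.00174 and Tnf -0.00302 (between doses). With DESeq2, Cxcl9 0.11 (400 µM against IL-4). With the replicate block, Il1b -0.12 (between doses). Leaving out 1 library gave these ranges. With IL-4 they were Acta2 -0.0327 to 0.30, Csf3r -0.38 to 0.0879, Mpo -4.38 to 2.76, Ppbp -1.13 to 0.17, S100a8 -0.82 to 1.75, S100a9 -1.19 to 1.78 and Treml1 -0.29 to 0.11. Between the doses they were Atp6v0d2 -0.25 to 1.65, Cd2 -0.36 to 0.42, Cd74 -0.43 to 0.11, Ciita -1.81 to 0.16, Cxcl12 -2.70 to 0.38, Cxcl3 -0.46 to 4.67, Fth1 -0.11 to 0.39, Gp1bb -0.80 to 0.12, H2-Ab1 -0.50 to 0.0239, Il10 -0.56 to 0.0736, Il1b -0.90 to 0.64, Itgax -0.10 to 2.44, Kdr -0.0719 to 0.67, Mcm5 -0.63 to 0.00367, Mmp12 -0.0935 to 3.33, Mpo -1.27 to 2.02, Mt2 -0.40 to 2.98e-04, Pecam1 -0.00735 to 0.61, S100a8 -0.0298 to 1.898, S100a9 -0.47 to 2.30, Slc40a1 -0.23 to 0.0531 and Tnf -0.12 to 0.0790. At 200 µM they were Cd74 -0.20 to 0.34, Cd86 -0.34 to 0.0507, Lck -0.64 to 0.42, S100a9 -2.39 to 0.19, Tnf -0.16 to 0.00374 and Treml1 -0.41 to 0.60. At 400 µM they were Cd74 -0.26 to 0.0703, Chil3 -1.10 to 0.84, Cxcl12 -0.0847 to 2.17 and Ngp -2.74 to 0.58. For 400 µM against IFN-γ the range was Chil3 -2.39 to 0.20. With IFN-γ they were Chil3 -0.53 to 2.45, Fth1 -0.0719 to 0.52, Marco -2.95 to 0.28, Ngp -1.79 to 0.38 and Retnla -1.96 to 7.12. For 400 µM against IL-4 the range was Il1b -0.84 to 0.70.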

Other observations

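The genes of the next 2 paragraphs were chosen after their values were seen, and so were all tests below except those of a stronger response (to heme-albumin, to IFN-γ) and the splits of the samples. The genes of complement C1q stood lower at 400 µM heme-albumin. C1qa, C1qb and C1qc, the chains of the complement starter, fell (-3.17 ± 0.81, -2.43 ± 0.65 and -2.70 ± 0.67, log2 fold change ± SE, n = 3 per group). The scavenger receptor Stab1 (-1.55 ± 0.48), the folate receptor Folr2 (-1.70 ± 0.42), the lipid carrier Apoe (-2.31 ± 0.75) and Tmem176b (-3.71 ± 0.65) fell too. The lipoprotein lipase Lpl rose (1.54 ± 0.17). At 200 µM the 3 C1q genes did not pass (-1.51 ± 0.76, -1.18 ± 0.62 and -1.28 ± 0.64), nor did they with IL-4 (-1.005 ± 0.75, -0.41 ± 0.62 and -0.32 ± 0.63) or IFN-γ (0.73 ± 0.75, 0.91 ± 0.62 and 1.04 ± 0.63). C1qa differed by -1.65 ± 0.77 between the doses (adjusted p = 0.331). Stab1 lost its call without control 1 (0.0697), control 2 (0.0505), control 3 (0.0810) and with no filter, range 0.0175 to 0.0810. Apoe lost its call without control 1 (0.0654), control 2 (0.0678), control 3 (0.0898) and 400 µM 1 (0.0832), 400 µM 2 (0.126) and with no filter, range 0.00610 to 0.126.

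IFN-γ also raised the dendritic cell receptor Clec9a (1692-fold higher, counting interval 303 to 66849), the nuclease Dnase1l3 (9.69 ± 0.37) and the prostaglandin synthase Ptgs2 (8.11 ± 0.66). The added fit of only the 6 heme-albumin libraries with the replicate block separated the doses at 236 genes, and the block in the fit of all 15 at 0 (smallest adjusted p 0.0719). The smallest adjusted p was 5.67e-04, for Mmp12 (log2 fold change 1.66), and Abca1 (-1.32), Apoe (-1.53), Ighm (-1.60) and Ptgs2 (1.19) were called too. In the fit of all 15 libraries Mmp12 stood at 1.56 ± 0.89, and without replicate 2 at 400 µM at -0.0935.

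Both replicate 2 libraries of the heme-albumin groups departed from their groups together. A difference between the dates shared by all groups is argued against, since their deviations correlated with those of the other replicate 2 libraries by a median of -0.0529 over 6 pairs. A shift of both toward the higher dose was prompted by the genes of the blocked fit standing high in those libraries, and it is in line with a median correlation of 0.337 over 4 comparisons that share no library (0.266 to 0.360), against -0.195 to -0.0160 in the other groups. A generally stronger response to heme-albumin on that date stays open, with a median of 0.216 over values from 0.400 to -0.0253, because the 200 µM and 400 µM libraries differ.

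Cell cycle genes were lowest in IFN-γ replicate 3, at a list median of 3.26 log2 CPM against 6.25 and 5.50 in replicates 1 and 2. A difference between the dates is argued against, because replicate 3 minus replicate 2 had a median of 0.0588 over the other 4 groups, against -2.24 with IFN-γ. Other cells in place of macrophages are argued against too, because core macrophage genes stood higher there by a median of 0.426 (quartiles 0.108 and 1.26). A stronger response to IFN-γ in that culture stays open, with correlations of 0.236 and 0.146 (median 0.191), too few values to decide.

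Type I interferon genes were lower at 400 µM than in controls, a list call lost with an estimated correlation (adjusted p = 0.0554). A few genes taking more of the counts are argued against, since without scaling the median of all genes moved by -0.186, far less than the list. A control library high in interferon genes is argued against by the list median of -1.84 without control 2, the nearest to 0 of the 3 (-2.27 and -2.30 without controls 1 and 3). A difference between the dates is argued against by the list median within each date, -1.96, -2.17 and -1.83. A response to heme-albumin and controls that were high as a group both stay open, since every treatment was set against the same 3 controls. The list was lower with IL-4 too (median -3.32), and it stood higher at 400 than at 200 µM (median 0.41), though with 0 of 20 genes called and an adjusted p of 0.886 with an estimated correlation. Further untreated cultures would be needed to tell these apart.

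Other splits of the same 6 libraries were too few for a share under 0.05, with 10 per comparison. The real split called 3017 genes at 400 µM, 2783 at 200 µM, 3179 with IL-4, 5165 with IFN-γ, 4779 for 400 µM against IL-4 and 5084 against IFN-γ, and in each comparison 1 split of 10, the real one, gave as many, with 0 as the highest other. Between the doses all 10 splits gave 0. Of the splits, 4 part every pair of the same number, and the highest other among them was 0 too.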
